A study of Mus musculus with 36 samples.

How the data were processed

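Heart apex from mice labelled cK15 and from control mice carrying the alpha-MHC cre transgene was profiled by RNA sequencing. The cK15 hearts lack Klf15 (Kruppel-like factor 15, a zinc-finger transcription factor). Only heart was sampled, so Klf15 in other tissues was not measured. Both genotypes were sampled at 6 times of day, 4 h apart, with 3 libraries per genotype and time, which makes 12 groups, 18 libraries per genotype and 36 in all. Per the labels' protocols, the animals were C57BL/6J males aged 11 to 12 weeks, kept in cycles of 12 h light and 12 h dark. RNA was extracted with Trizol and miRNeasy columns. From each extract, 1 ug was depleted of ribosomal RNA with Ribo-Zero, and stranded total RNA libraries (TruSeq) were sequenced as 100 bp pairs on an Illumina HiSeq in pools of 3. Ribosomal depletion keeps unspliced and non-polyadenylated RNA, so that gene values can include intronic and nuclear transcripts where the counting took them in. The clock time of lights-on is not given in the sources used here. Labels of 12 am were read as midnight and 12 pm as noon.

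The authors deposited FPKM (fragments scaled to gene length and to the library's total) in a table for each genotype, with a value per gene symbol and library. Per the submitters' processing notes, GSNAP, HTSeq and the mouse build mm10 were used. Their versions and roles, the annotation and the program that computed FPKM are not given in the sources used here. FPKM divides by gene length and by library total, so a few very abundant genes can lower the values of all others. The tables listed the same 23352 gene entries in the same order. Of these, 27 symbols had been turned into dates by spreadsheet software and 2 symbols occurred more than once, and these were tested but are not named. No whole-read step was recovered from the low values, so the depth of the libraries is unknown and no counting interval or detection floor is given. The FPKM of a library summed to between 534039 and 691583, with 13809 to 15395 genes above 0. An exact 0 was not always a true absence: Ttn, which encodes the giant muscle protein titin, was listed at 0 in all 36 libraries, and the ribosomal precursor Rn45s at 0 in all 3 control libraries of 8 pm. A gene at 0 is therefore only said to be listed at 0. The 2 tables were treated as FPKM computed per library and compared directly. The median log2 fold change between them over all tested genes was -0.012.

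Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 10599 genes with a mean FPKM of at least 1 over the 36 libraries, with variance moderation that follows mean expression and is robust to outlying genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level. Genotypes were compared with 12 group means, as the average over the 6 times and at each time. Rhythm was tested within each genotype's own 18 libraries by a cosine and a sine of clock hour with a 24 h period. The difference in rhythm between genotypes was tested by the genotype terms of that curve over all 36 libraries. Amplitudes are on the log2 scale, from the mean of the curve to its peak. Klf15 itself had a mean below the filter and was added to the tested genes for its own test. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

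Before the data were examined, 14 gene lists (core clock and clock output, branched-chain amino acid catabolism, fatty acid uptake and oxidation, glucose uptake and glycolysis, oxidative phosphorylation, glucocorticoid-responsive, hypertrophy and fetal programme, extracellular matrix and fibrosis, ion channels and calcium handling, Kruppel-like factors, autophagy and protein degradation, heat shock and protein folding, immediate early, proliferation) and 15 marker lists (cardiomyocyte, fibroblast, endothelial, smooth muscle and pericyte, macrophage, lymphocyte, blood, atrial, adipocyte, Schwann and nerve, mesothelial, skeletal muscle, sex, mitochondrial genome RNA, nuclear retained RNA) were fixed. For the averaged genotype difference they were tested with camera, preset correlation 0.01, and again with an estimated correlation; enrichment among rhythmic genes was tested with a two-sided Fisher exact test against all tested genes. List p-values were adjusted within the 14 or the 15 lists. Per1 is in the clock and the glucocorticoid list, Klf9 in the glucocorticoid and the Kruppel-like list, and Ctgf in the hypertrophy and the matrix list. Genes named in the text follow a rule fixed at the same time: the 10 highest and 10 lowest fold changes among averaged calls, up to 4 called members of each list with the smallest adjusted p, the 3 highest and 3 lowest calls at each time, all measured clock genes, the 10 rhythmic genes of largest amplitude in each genotype, up to 3 rhythmic members of each list, and the 10 smallest p for the difference in rhythm. Predicted genes, clones, small RNAs and pseudogenes were counted but not named. Genes named outside that rule were chosen after their values were seen: Ttn, list members described as not past the threshold, the genes that mark the 12 libraries standing apart, and genes of the closing part. The averaged calls of Auh and Ppargc1a, which rose against their lists, were also named outside it. These calls were not recomputed in the alternative settings for named genes.

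The steps were tested on simulated data made from the 10599 genes with 100 genes changed at each size. The changed genes were drawn only from genes of higher mean level. Noise was drawn independently for each gene and library, so variation shared by the genes of a library was not reproduced. The recoveries below do not cover genes of low level or such shared variation. For the averaged genotype difference 78% of genes changed by 1.25-fold and 99% of those changed by 1.5-fold were recovered; at a single time it was 56% at 1.5-fold and 91% at 2-fold. Rhythms of amplitude 0.2 were recovered in 23% and of amplitude 0.4 in 79% of genes, and a rhythm of amplitude 0.4 that was lost in the other genotype gave a call in 65%.

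Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, median-ratio and quantile rescaling, plain variance moderation, a minimum fold of 1.5, a replicate block, an additive model, separate or joint fits, other rhythm models, exchange of noon and midnight, and leaving out each library or each replicate number of a genotype. Named genes were recomputed with the pseudocount, both rescalings, plain variance moderation, a term for 2 library sets and each omission, and named genotype differences with the replicate block too, which makes 48 settings for a genotype difference and 26 for a rhythm. Principal components of the libraries' deviations from their group means showed 12 libraries apart from the other 24; terms for these library sets, fits in either set alone, and the replicate block for named genes were chosen after seeing the data. The genotypes share replicate numbers 3 and 4 in the labels. Deviations from group means of all 12 same-numbered pairs correlated across genes by over 0.1 (0.157 to 0.508), and in 11 of 12 pairs both libraries correlated best with their own number, so the numbers were taken to pair the libraries between genotypes. This pairing comes from the data, and the 12 libraries standing apart contribute to it, since they mostly hold the numbers that the genotypes do not share. In the replicate block, number 1 (cK15 only) and number 2 (control only) take terms of their own. With the block, the averaged difference therefore rests on numbers 3 and 4 alone, and a lost call can reflect the fewer libraries. All 36 pairs of libraries within groups differed, with correlations of log2 values between 0.975 and 0.989 and 0 identical pairs. Gene positions are from a RefSeq gene table of build GRCm38 (mm10), matched by symbol or synonym for 23171 of 23350 symbols. Transcript length and GC content are from the GENCODE annotation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.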

Results

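RNA of the heart apex was measured in 36 libraries, 18 from hearts without Klf15 (cK15) and 18 from hearts of control mice. The control mice carried the alpha-MHC cre transgene, which drives recombination in heart muscle cells. Each genotype was sampled at 12 am, 4 am, 8 am, 12 pm, 4 pm and 8 pm with 3 libraries per time, to compare the circadian transcriptome of the genotypes. Values were FPKM as deposited. Depth was unknown, and 10339 to 10829 genes per library had an FPKM of at least 1.

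Klf15, on chromosome 6 at 90461043 to 90491803 (GRCm38), was at 1.45 ± 0.727 FPKM in control hearts (SD, n = 18), with every library between 0.406 and 2.91. In cK15 hearts it was listed at 0 in 13 of 18 libraries, and the highest of the other 5 reached 0.326. The averaged log2 fold change was -1.16 (SE 0.097; limma adjusted p = 2.16e-10), and every cK15 library lay below every control library, as the labels state. Within control, the mean was highest at 8 pm (2.35 ± 0.715, SD, n = 3) and lowest at 8 am (1.07 ± 0.152, SD, n = 3), but a 24 h rhythm did not pass the threshold (amplitude 0.27, SE 0.12; limma adjusted p = 0.509).

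**Figure D1:**
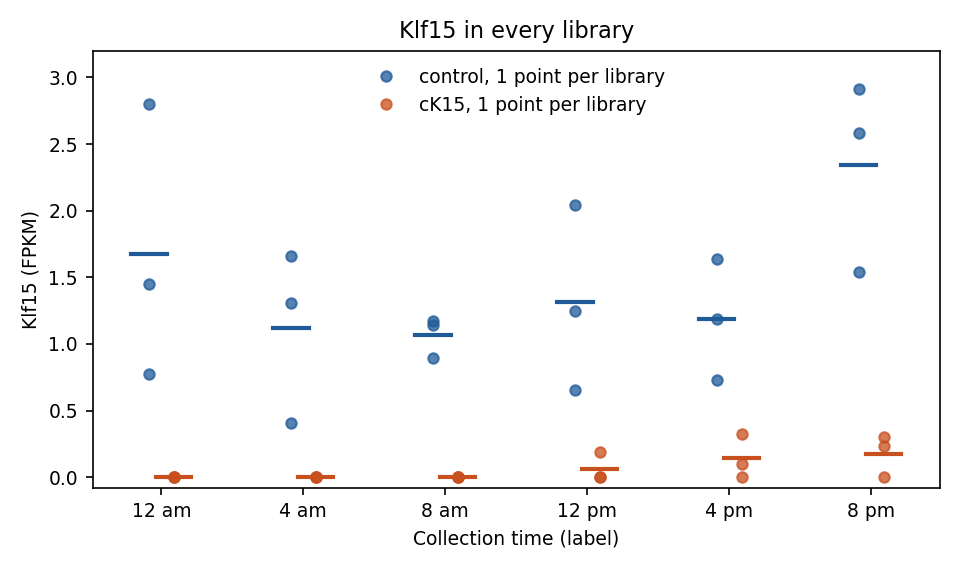
Klf15 in FPKM (vertical axis) at each collection time (horizontal axis) in control and cK15 hearts, with a point per library and a line at the mean of 3 libraries. The control points lie between 0.406 and 2.91 and the cK15 points between 0 and 0.326.

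Adhfe1, Gstm2, Gstk1, Fah, Bdh1, Ccbl2 and Cth were among the 10 genes with the lowest averaged fold change in hearts without Klf15. Adhfe1, a mitochondrial enzyme that oxidises 4-hydroxybutyrate, fell from 66.0 ± 12.3 to 3.08 ± 0.719 FPKM (SD, n = 18 each; log2 fold change -4.04, SE 0.080). The glutathione transferases Gstm2 (155 ± 12.3 to 18.3 ± 3.94 FPKM, SD) and Gstk1 (211 ± 19.4 to 29.7 ± 3.97 FPKM, SD) fell by 3.04 and by 2.79 on the log2 scale. Fah, the last enzyme of tyrosine breakdown, changed by -2.34 (SE 0.10), Bdh1, which interconverts the ketone bodies, by -2.27 (SE 0.17), and the kynurenine aminotransferase Ccbl2 by -2.02 (SE 0.045). Cth, which makes cysteine and hydrogen sulfide, was between 1.68 and 6.02 FPKM in control and listed at 0 in 16 of 18 cK15 libraries, the other 2 at 0.154 and 0.232.

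Pttg1 (securin), Cyfip2 (a subunit of the WAVE complex that controls actin) and Fndc9 completed the 10 lowest genes, with log2 fold changes of -3.48 (SE 0.39), -2.48 (SE 0.29) and -2.05 (SE 0.21). Pttg1 and Cyfip2 spread widely among cK15 libraries, from 6.19 to 136 FPKM and from 2.69 to 36.5 FPKM, below every control library (at least 212 and 44.8). They lie on chromosome 11 at 43420244 to 43427463 and 46193849 to 46312859, and Fndc9, at 46235557 to 46239871, lies within Cyfip2, so reads in the overlap cannot be assigned where counting ignored strand. Gstm2 has close copies among the other mu-class transferases, and its value is uncertain where reads were split between them. Adhfe1 is on chromosome 1 at 9547948 to 9577970, Gstm2 on chromosome 3 at 107981702 to 107986420 and Gstk1 on chromosome 6 at 42245935 to 42250441.

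Fewer genes rose strongly. Pigh, which acts in GPI anchor synthesis, rose from 2.15 ± 0.699 to 7.18 ± 2.46 FPKM (SD, n = 18 each; log2 fold change 1.36, SE 0.11), and its neighbour Plekhh1 by 0.81 (SE 0.067). Pigh at 79080669 to 79089753 on chromosome 12 overlaps Plekhh1 at 79029163 to 79081655, so the assignment of reads there is uncertain. The endosomal GTPase Rab4a rose by 0.99 (SE 0.12) and the telomere protein Ten1 by 0.79 (SE 0.10). The phosphorylase kinase subunit Phkg1 rose by 0.72 (SE 0.068), the phosphatase Cdc14b by 0.68 (SE 0.12) and the insulin-degrading enzyme Ide by 0.67 (SE 0.092). Ptprn2, a protein of secretory vesicles, was at most 0.145 FPKM in control and between 0 and 11.6 FPKM in cK15 (log2 fold change 1.70, SE 0.29). Erdr1 (3.91, SE 0.39) and Rn45s (1.78, SE 0.43) had the highest fold changes. Both come from repeated sequence, and Erdr1 was listed at 0 in 14 of 18 control libraries and Rn45s in 3, so their sizes are uncertain.

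Averaged over the 6 times, 1191 of 10599 genes passed the threshold (11.2%), 430 higher and 761 lower in cK15. The split depended on scaling: median-ratio rescaling gave 565 higher and 658 lower, and quantile normalization 635 higher and 605 lower. At a minimum of 1.5-fold 18 genes were higher and 126 lower, and at a minimum of 2-fold 5 were higher and 43 lower. Treating each genotype's replicate number as a random series left 346 genes (94 higher, 252 lower), and leaving out control replicate 3 at all times left 757.

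Within the groups, 12 libraries stood apart from the other 24. They were 1 library of every group, cK15 replicate 1 and control replicate 2 at 5 times and replicate 4 of both genotypes at 8 pm, so both genotypes held 6. In the 12, Myl2 (the ventricular myosin light chain) was between 29700 and 35773 FPKM against 43872 to 71845 in the 24, and the 10 most abundant genes took 15.8% to 16.9% of the summed FPKM against at least 21.6%. The cardiomyocyte markers differed by a median of -0.60 log2. All 1191 genes called over the 36 libraries had the same sign in the 12 and in the 24 libraries. These genes were chosen on the same libraries, so this adds no independent support. The 24 alone gave 1175 calls; the 12 alone, with 1 library per group, gave 575 in an additive genotype and time model instead of 12 group means. A term for the library set gave 2168 calls (904 higher, 1264 lower), which included all 1191. The sets were defined from these data and held 1 library of every group. The term therefore left the fold changes as they were and could change only the estimate of the spread. That the 1191 were kept was nearly fixed in advance.

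**Figure D2:**
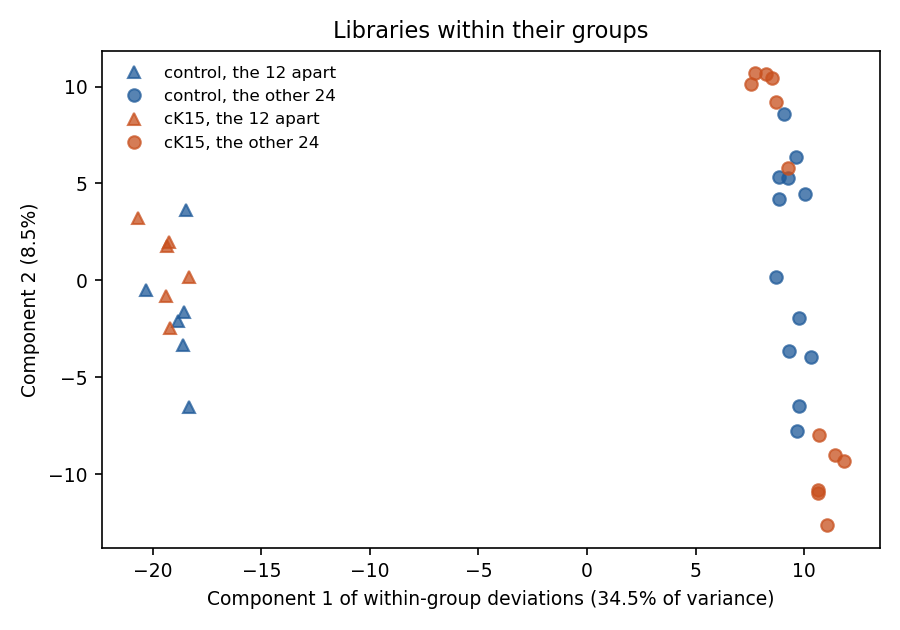
First and second principal component (horizontal and vertical axis, component scores) of the deviations of log2(FPKM + 1) from the group means, with a point per library; the components hold 34.5% and 8.5% of the variance. The 12 libraries apart lie between -20.7 and -18.4 on the first component and the other 24 between 7.53 and 11.9, with 6 libraries of each genotype among the 12.

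Genes that break down branched-chain amino acids fell together in cK15 hearts. Of 20 measured, 15 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 1.44e-28, and adjusted p = 5.31e-06 with an estimated correlation). Bckdhb and Bckdha, which encode the E1 subunits of the branched-chain ketoacid dehydrogenase, changed by -1.55 (SE 0.056) and -0.97 (SE 0.044). The mitochondrial aminotransferase Bcat2 changed by -1.18 (SE 0.045), and isovaleryl-CoA dehydrogenase, Ivd, from 281 ± 26.9 to 123 ± 7.74 FPKM (SD, n = 18 each; -1.18, SE 0.032). Auh, a hydratase of leucine breakdown, rose by 0.12.

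The fatty acid list fell as well: 23 of 31 genes fell and 1 rose (24 and 1 adjusted over the list alone; camera adjusted p = 2.39e-23, and adjusted p = 0.00028 with an estimated correlation). Lpl, the lipase that frees fatty acids from circulating lipoproteins, changed from 626 ± 86.4 to 351 ± 28.5 FPKM (SD, n = 18 each; -0.82, SE 0.043). Pdk4, which restrains glucose oxidation, changed by -1.53 (SE 0.12), the carnitine carrier Slc25a20 by -0.58 (SE 0.045) and the acyl-CoA thioesterase Acot1 by -1.25 (SE 0.11), with Acot1 uncertain because of its close copy Acot2. Ppargc1a, a coactivator of mitochondrial genes, rose by 0.14.

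**Figure D3:**
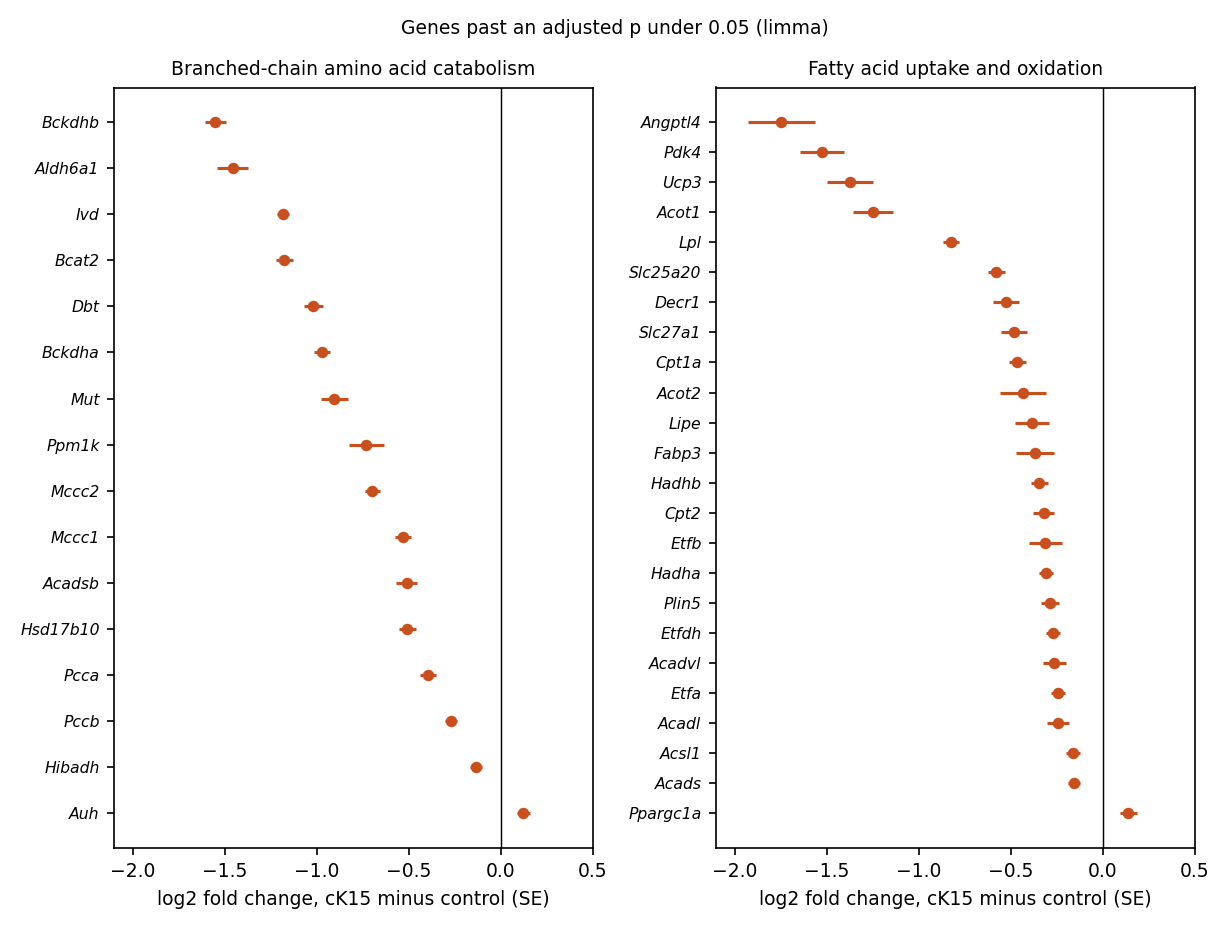
Averaged log2 fold change, cK15 minus control, with its standard error (horizontal axis) for each gene (vertical axis) of the branched-chain amino acid list and the fatty acid list that passed an adjusted p under 0.05. Of the points, 15 and 23 lie below 0, and 1 in each list lies above 0.

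Other metabolic lists did not move as a whole. Of 20 glucose genes 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.404), with median 0.024 and mean -0.076 log2. The bifunctional glycolytic regulator Pfkfb1 fell from 8.31 ± 3.16 to 1.27 ± 0.542 FPKM (SD, n = 18 each), and its relative Pfkfb2 rose by 0.27. Phosphofructokinase Pfkm rose by 0.23 and lactate dehydrogenase Ldhb fell by 0.24, a call lost in 9 of 48 settings. Of 18 oxidative phosphorylation genes the heart isoform Cox6a2 fell by 0.83 and Uqcrc1 rose by 0.10, the same count adjusted over the list alone (camera adjusted p = 0.0677; median 0.055, mean -0.0041). With the replicate block this list passed the camera threshold towards higher expression (adjusted p = 0.00648). Median-ratio rescaling gave 3 higher and 1 lower gene in it, and quantile normalization 4 higher and 2 lower. In the glucose list the same rescalings gave 4 higher and 1 lower, and 2 higher and 2 lower. The 16 clock genes had 0 calls, and 0 adjusted over the list alone (limma; 2 at unadjusted p under 0.05; camera adjusted p = 0.136); both rescalings gave 2 higher clock genes.

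Among heart gene lists, the channel subunit Kcnip2, a partner of the Kv4 potassium channels, fell from 85.1 ± 7.60 to 55.7 ± 4.48 FPKM (SD, n = 18 each; -0.60, SE 0.041; chromosome 19, 45792346 to 45816422). The pacemaker channel Hcn2 (0.39), the calcium channel Cacna1c (0.28) and the potassium channel Kcnd3 (0.30) were among 5 that rose. The list held 19 tested genes (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.301). The hypertrophy list of 10 had 1 gene past the threshold, cardiac actin Actc1, which rose by 0.15 (5 higher and 0 lower adjusted over the list alone). Camera placed the list higher (adjusted p = 0.00205), which was lost with an estimated correlation (adjusted p = 0.158 with an estimated correlation) and without control replicate 2 (adjusted p = 0.0661). Median-ratio rescaling gave 4 and quantile normalization 3 higher genes in this list, and Nppa and Nppb did not pass (limma adjusted p = 0.059 and 0.0501). Of 16 matrix genes 4 fell and 0 rose (9 lower and 1 higher adjusted over the list alone): the collagens Col3a1 (-0.48), Col5a2 (-0.31) and Col1a1 (-0.50) and the protease inhibitor Timp1 (-0.66). Camera placed the matrix list lower (adjusted p = 0.00446), which was lost with an estimated correlation (adjusted p = 0.260 with an estimated correlation). Of 12 glucocorticoid-responsive genes Tsc22d3 (0.40) and Ddit4 (0.48) rose and Glul (-0.32) and Klf9 (-0.26) fell (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.301; median -0.012, mean 0.065). The Klf9 call was lost in 29 of 48 alternative settings, the replicate block among them (limma adjusted p = 0.0798).

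Among markers of other cells of the heart, 4 of 7 fibroblast and 7 of 9 macrophage genes passed the threshold, all lower in cK15. Of 7 fibroblast markers Dcn (-0.21), Gsn (-0.19), Lum (-0.31) and Pdgfra (-0.18) fell (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.000363, and adjusted p = 0.0644 with an estimated correlation). Of 9 macrophage markers 7 fell, among them Emr1 (-0.29), Lyz2 (-0.31), Mrc1 (-0.22) and C1qb (-0.30), and 7 adjusted over the list alone (camera adjusted p = 0.000363, and adjusted p = 0.148 with an estimated correlation); both rescalings left 4. Endothelial markers had 0 of 7 past the threshold and 3 lower adjusted over the list alone (limma; 5 at unadjusted p under 0.05; camera adjusted p = 0.0396, and adjusted p = 0.148 with an estimated correlation). The cardiomyocyte list had 1 of 8 higher, creatine kinase Ckm (0.22), whose call was lost in 32 of 48 settings, and 1 adjusted over the list alone (camera adjusted p = 0.330, and 0.0462 with a term for the library set). Median fold changes of the fibroblast, macrophage and endothelial lists were -0.19, -0.24 and -0.12 log2, and all 3 stayed below 0 under both rescalings.

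At each single time more genes were lower than higher in cK15, on FPKM as deposited. The averaged split depended on scaling, and the splits at single times under rescaling are not given here. Adhfe1 was among the 3 lowest genes at every time, between -4.42 at 4 am (SE 0.20) and -3.76 at 8 am (SE 0.20), and Gstm2 was among the 3 lowest at every time but 8 am, between -3.37 at 12 am and -2.79 at 12 pm (SE 0.13 each). Gstk1 joined them at 12 am (-2.94), 4 am (-2.93), 12 pm (-2.67) and 4 pm (-2.90; SE 0.14 each). Others among the lowest were Pttg1 at 8 am (-4.60, SE 0.95) and 8 pm (-4.07, SE 0.95), and Cyfip2 at 8 am (-2.93, SE 0.71). Pigh was among the 3 highest at 12 am, 4 am, 8 am, 12 pm and 4 pm, at most 1.80 (4 pm, SE 0.27). The prostaglandin D synthase Ptgds rose at 12 am (1.15, SE 0.22), and the acyl-CoA synthetase Acsl6 at 4 am (0.83) and 12 pm (0.77; SE 0.17 each). Kbtbd12 (1.07, SE 0.26) and Phkg1 (0.95, SE 0.17) rose at 8 am, and Plekhh1 at 12 pm (1.11, SE 0.16). The nuclear receptor Nr4a1 (1.17, SE 0.29) and Hsd11b1, which regenerates active glucocorticoid (1.02, SE 0.20), rose at 4 pm. The calls of Cyfip2 at 8 am, Pttg1 at 8 pm, Kbtbd12 at 8 am, Nr4a1 at 4 pm and Acsl6 at 4 am and 12 pm were lost in 10, 9, 8, 12, 5 and 8 of 48 settings, that of Cyfip2 with the replicate block as well (limma adjusted p = 0.0724).

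At 8 pm the natriuretic peptide gene Nppb was at 305 ± 23.9 FPKM in cK15 and 148 ± 107 in control (SD, n = 3 each; log2 fold change 1.27, SE 0.32), a call lost in 35 of 48 settings, the replicate block among them (limma adjusted p = 0.0940). Erdr1 at 12 am, 4 am and 8 pm and Rn45s at 8 pm were among the highest calls against control libraries all listed at 0, so no fold is given; the cK15 libraries lay between 19.4 and 48.2 FPKM for Erdr1 and between 230 and 1044 for Rn45s.

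The higher and lower calls were 12 and 116 at 12 am, 17 and 102 at 4 am, 18 and 94 at 8 am, 5 and 74 at 12 pm, 21 and 117 at 4 pm, and 25 and 94 at 8 pm. All 48 genes that passed at all 6 times were lower in cK15. Branched-chain genes made up 14, 11, 10, 9, 10 and 10 of the lower calls in the same order of times, and fatty acid genes 12, 6, 4, 1, 10 and 6; whether these counts differ between times was not tested. A term for the library set gave 40 and 215, 53 and 175, 58 and 158, 36 and 115, 92 and 224, and 89 and 185 higher and lower calls in that order, which raised the share of higher calls, at 12 pm from 6.33% to 23.8%. In the 24 libraries that did not stand apart the totals were 120, 102, 134, 76, 122 and 87. The 12 others hold 1 library per group, too few for a test at a single time. Totals moved by over 1.5 times without single libraries: at 8 am to 73 without control replicate 3 (from 112), at 4 pm to 86 and 88 without control replicates 3 and 4 (from 138), and at 8 pm to 73, 76, 78 and 76 without cK15 replicates 1 and 3 and control replicates 2 and 4 (from 119).

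Clock genes cycled strongly in both genotypes. Of 16 measured, 15 were rhythmic in control and 14 in cK15 (16 and 15 adjusted over the list alone; Fisher exact adjusted p = 7.94e-22 and 2.01e-25). Arntl (Bmal1; chromosome 7, 113178471 to 113314126), the core activator of the clock, had an amplitude of 1.85 (SE 0.10) in control and 2.02 (SE 0.13) in cK15 on the log2 scale, Dbp, an output activator, 1.63 (SE 0.097) and 1.59 (SE 0.13), and the repressor Per2 (chromosome 1, 91415977 to 91459351) 1.12 (SE 0.074) and 1.13 (SE 0.073). Cry2 was rhythmic in control alone, a call lost in 12 of 26 settings, and Rora in neither; neither differed between genotypes (unadjusted p = 0.480 and 0.227).

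Outside the clock list the sphingosine kinase Sphk2 (amplitude 1.59 in control and 1.48 in cK15), the matrix protein Spon2 (1.05 and 0.88), the sarcomere protein Tcap (1.03 and 0.83), the glutathione transferase Gsta3 (0.98 and 0.81), the magnesium carrier Slc41a3 (0.96 and 0.95) and the collagen Col5a3 (0.96 and 0.98) were among the genes of largest amplitude. Sphk2 at 45709463 to 45718002 on chromosome 7 overlaps the clock gene Dbp at 45705100 to 45710203. The assignment of reads there is uncertain, and the rhythm of Sphk2 may not be separate from that of Dbp. Nppb had an amplitude of 1.02 (SE 0.15) in control and 0.57 (SE 0.097) in cK15, rhythmic in both.

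**Figure D4:**
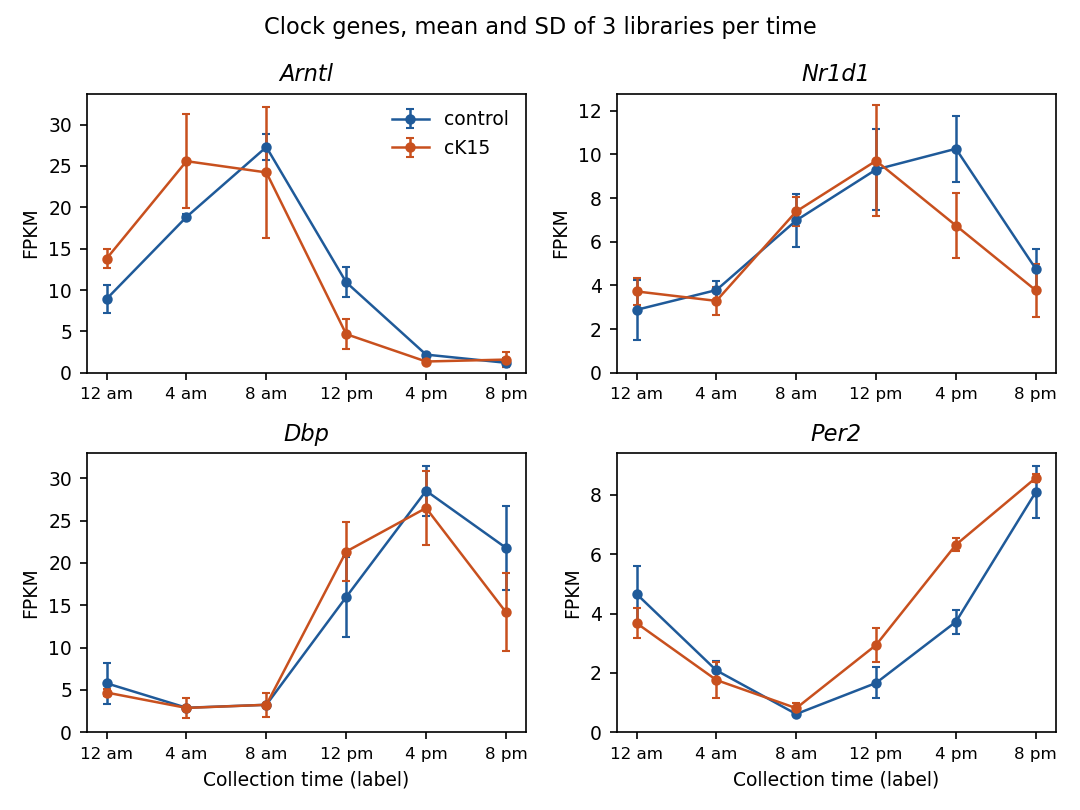
Mean FPKM and SD of 3 libraries (vertical axis) of Arntl, Nr1d1, Dbp and Per2 at each collection time (horizontal axis) in control and cK15 hearts. Per2 has its highest mean at 8 pm in both genotypes (8.10 and 8.57 FPKM), and at 4 pm it is at 6.32 in cK15 and 3.73 in control.

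A further 3 lists held more rhythmic genes than other tested genes did. The Fisher tests of rhythm take genes as independent, so their p-values may be too small. In the averaged genotype fit the estimated correlation within these lists was 0.443 (glucocorticoid-responsive), 0.185 (hypertrophy) and 0.225 (matrix). Of 12 glucocorticoid-responsive genes 5 were rhythmic in control and 3 in cK15 (7 and 9 adjusted over the list alone; Fisher exact adjusted p = 7.88e-05 and 0.00174). Zbtb16 (amplitude 0.82 in control) and Tsc22d3 (0.55) were called in control, beside Per1 of the clock list (0.77). Of 10 hypertrophy genes it was 4 and 2 (5 and 3 adjusted over the list alone; 0.000518 and 0.0171). Rcan1, an inhibitor of calcineurin, was at 0.57 in control and 0.62 in cK15, and the natriuretic peptide Nppa at 0.77 in control. Of 16 matrix genes it was 4 and 3 (12 and 5 adjusted over the list alone; 0.00295 and 0.00286), among them Col3a1 (0.62 and 0.52), Timp1 (0.68 in control) and Thbs1 (0.42 and 0.44). The control calls of Nppa, Timp1 and Thbs1 were lost in 21, 10 and 16 of 26 settings.

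No branched-chain gene passed the rhythm threshold of limma in either genotype (0 of 20; 7 in control and 0 in cK15 at unadjusted p under 0.05; 4 and 0 adjusted over the list alone), and of fatty acid genes only Ppargc1a in control (amplitude 0.28, SE 0.044; 0.060, SE 0.054 in cK15; 1 and 1 adjusted over the list alone). With a term for the library set, 6 branched-chain genes passed in control and 0 in cK15, and 4 and 1 fatty acid genes. The glycolytic genes Pfkfb2 (0.28) and Pfkp (0.28), the channel gene Kcnh2 (0.32, lost in 17 of 26 settings), the autophagy receptor Sqstm1 (0.25), the endothelial receptor Kdr (0.48) and smooth muscle actin Acta2 (0.64) were rhythmic in control; Sqstm1 and Kdr also passed in cK15. None of these differed between genotypes after adjustment.

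In all, 297 genes were rhythmic in control (1486 at unadjusted p under 0.05) and 114 in cK15 (949), and 81 were in both, where 3.19 would be shared if the calls were independent. With a term for the library set there were 730 and 261; the 24 libraries that did not stand apart gave 240 and 76, and the 12 others 46 and 7. Time as a factor of 6 levels gave 143 and 42, 24 h and 12 h periods together 136 and 57, and 12 am read as noon and 12 pm as midnight, a reading that no source used here settles, 44 and 28; a minimum of 1.5-fold left 191 in control, and all 36 libraries in 1 fit gave 202 in cK15. Leaving out a replicate number at all times left 86 to 152 in control and 33 to 64 in cK15, and without cK15 replicate 4 of 8 am 75 in cK15.

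Fitted peaks lay earlier in cK15 than in control hearts. All 14 clock genes rhythmic in both genotypes had an earlier fitted peak, by a median of -1.61 h (-2.75 h for Per1 to -0.799 h for Dbp), with a median amplitude ratio of 0.956. Arntl peaked at clock hour 6.56 (SE 0.21) in control and 5.02 (SE 0.25) in cK15, and Cry1 at 1.97 (SE 0.36) and 0.379 (SE 0.44). Nr1d1 peaked at 13.1 (SE 0.43) and 12.0 (SE 0.53), Dbp at 16.7 (SE 0.23) and 15.9 (SE 0.32), and Per2 at 20.5 (SE 0.25) and 18.8 (SE 0.24). Of the 81 genes rhythmic in both, 78 peaked earlier and 3 later in cK15, with a median of -1.56 h and a median amplitude ratio of 0.920. Genes are not independent of each other, and no test was run across them.

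**Figure D5:**
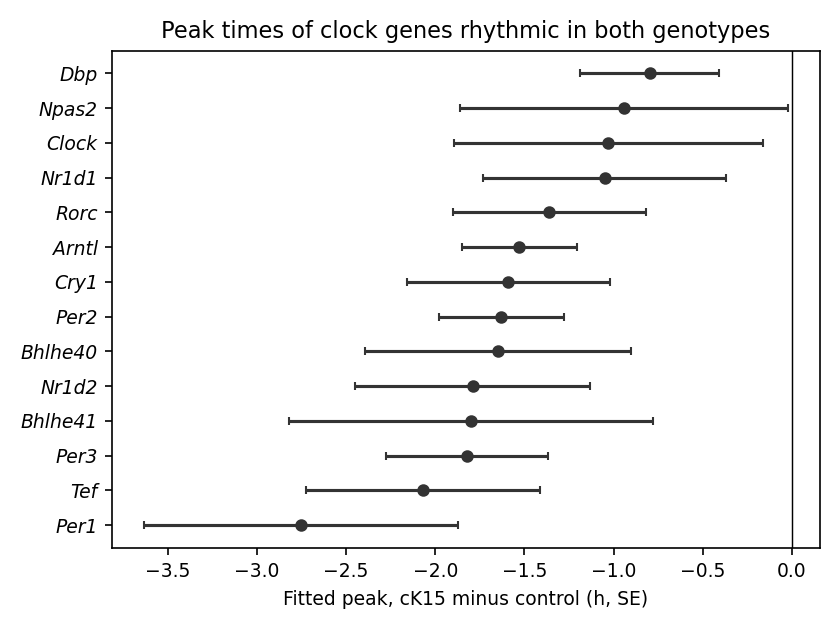
Difference of the fitted peak time, cK15 minus control, in hours with its standard error (horizontal axis) for each of the 14 clock genes rhythmic in both genotypes (vertical axis). All 14 points lie below 0, from -2.75 h for Per1 to -0.799 h for Dbp.

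Rhythmic genes of control peaked most often around 12 am (74 of 297, 24.9%) and 8 am (70, 23.6%), then 8 pm (49), 12 pm (47), 4 pm (35) and 4 am (22). In cK15, 32 of 114 peaked around 8 am (28.1%), 26 around 4 pm, 23 around 8 pm, 13 around 12 pm, 11 around 4 am and 9 around 12 am (7.89%). With a term for the library set the order in cK15 was 8 pm (22.6%), 8 am (21.5%) and 4 pm (21.1%), with 13.4% around 12 am. These shares describe the called genes of each genotype, and their difference was not tested. With noon and midnight exchanged, 0% of rhythmic control genes peaked around midnight. Sampling every 4 h limits the resolution of peak time.

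The test of the rhythm difference itself found 0 of 10599 genes past the threshold (limma; 291 at unadjusted p under 0.05). In this planned fit, adjusted over all genes, no gene was thus shown to cycle differently. Adjusted over the list alone, 3 of 16 clock genes, 1 branched-chain gene and 1 glucose gene passed, and 0 in the other gene lists. The smallest p-values belonged to Col5a3 (unadjusted p = 7.98e-05, limma adjusted p = 0.352), the skeletal troponin Tnnt3 (9.41e-05), Slc41a3 (0.000199), Per2 (0.000206), Gstm2 (0.000233) and Arntl (0.000273), followed by Pnck, Kifc3, Tmem194 and Commd6. Col5a3 had peaks at clock hour 8.89 (SE 0.26) in control and 7.13 (SE 0.24) in cK15. A term for the library set gave 1 gene, Usp2, a time factor of 6 levels 1, and the 24 libraries alone 2. Leaving out cK15 replicate 4 at all times gave 1, and the 12 libraries standing apart gave 0.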

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

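The tests of the count difference, the peak shift against other splits, the sampling time, the near-identical gene copies and the evenly balanced splits were chosen only after the results were seen, as were all terms for library sets.

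Redrawing the genotype within times gave as many genes as the 1191 of the averaged difference in 3 of 100 splits, the real one included. That share is under the 0.05 set beforehand but not adjusted for the number of tests, and the highest other split gave 2292. Both larger splits, with 2049 and 2292 genes, put 11 of the 12 libraries that stand apart into 1 group, which points to a structure of the samples. The 26 other splits with 6 such libraries in each group gave at most 0 genes (limma), and among splits that part every same-numbered pair the highest other gave 153. At single times, 1 of 10 splits (the real one) gave as many genes as the real 128, 119, 112, 79, 138 and 119; the highest others gave 1, 0, 0, 0, 1 and 0 (limma), and 10 splits are too few for a share under 0.05. Redrawing times gave as many rhythmic genes in 2 of 100 splits for control (real 297, highest other 1077) and 4 of 100 for cK15 (real 114, highest other 685). These shares are under 0.05 but not adjusted for the number of tests, and alone do not exclude chance. Redrawing times within the 3 library sets of a genotype, chosen afterwards, gave as many in 1 of 100 (the real one). The highest others were 1 gene in control and 6 in cK15. For the difference in rhythm the real count was 0 genes (limma; 291 at unadjusted p under 0.05), which 100 of 100 splits reach by construction, so this count says nothing about chance; the 844 genes of the highest other split point to a structure of the samples. The 183 more rhythmic genes in control than in cK15 were matched in 3 of 100 splits (highest other 269). That share is not adjusted for the number of tests either, and alone does not exclude chance. The lower amplitude in cK15 (median ratio 0.888 over 815 shared genes) was matched in 5 of 100, and chance cannot be excluded there.

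Tests of a time course that differed between genotypes picked out 6 genes. With time as a factor of 6 levels, Rn45s passed (limma adjusted p = 0.0214), with all 3 control libraries of 8 pm listed at 0. With a term for 2 library sets the deubiquitinase Usp2 passed (limma adjusted p = 0.00265). With 3 sets Usp2 (0.00102), the NAD synthesis enzyme Nampt (0.0171), the branched-chain gene Dbt (0.0379), Gpcpd1 (0.0379) and Col5a3 (0.042) passed. Single outlying libraries within the groups of 3 were not tested.

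The 12 libraries that stand apart held lower cardiomyocyte markers (median -0.60 log2), lower Tnnt2 (-1.17) and Tpm1 (-1.08), and higher Malat1 (1.12) and Lars2 (1.27). The ribosomal precursor Rn45s was higher too (1.31, mean 1290 against 497 FPKM). Nuclear retained RNA was higher in 4 of 4 genes (median 0.342) and the glucocorticoid-responsive list in 11 of 12 (0.369). Heat shock and protein folding genes were higher in 3 of 12 (-0.19). What these differences reflect was not tested. Cells of another type are argued against: the highest median of the 4 other marker lists was 0.132, below the 0.15 set beforehand. A GC or transcript length bias cannot be told apart from other sources, since the larger Spearman correlation across genes was 0.147, between the bounds set beforehand. A candidate explanation for part of the difference is that reads of near-identical gene copies were assigned differently. Of 76 ribosomal protein genes, 18 (23.7%) differed by over 0.5 log2, against 299 of 3791 other abundant genes (7.89%, Fisher exact p = 2.65e-05). The other genes were chosen by abundance and not matched in length, so this count does not separate gene copies from a length bias. Hba-a2 was at 101 ± 63.3 FPKM (SD, n = 12, range 0.0173 to 209) against 0.0603 ± 0.00385 (SD, n = 24). The sum with its copy Hba-a1 was 131 and 137. The labels give no batch, and the design names no biological difference between the 12 and the 24 libraries, so none was tested.

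Earlier peaks in cK15 had a median of -1.13 h over 815 genes. This was as extreme in 1 of 100 splits, the real one, and the highest other was 0.763 h in size. That share is under 0.05, in a test chosen after the shift was seen. If cK15 hearts had been taken later in the cycle than control hearts of the same label, clock genes and other genes would be shifted alike; the medians were -1.59 h for 13 clock genes and -1.62 h for 53 others, a difference of -0.033 h. Later sampling therefore stays open as a candidate explanation. An effect of the genotype on the clock would give the same shift, was not tested apart from it, and stays open too.

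Pttg1, Cyfip2 and Ptprn2 lay at 2 separate levels among cK15 libraries. Pttg1 was between 119 and 136 FPKM in 5 libraries and between 6.19 and 15.7 in the other 13, Cyfip2 between 24.3 and 36.5 in 5 and between 2.69 and 12.2 in 13, and Ptprn2 (chromosome 12, 116485695 to 117278167) between 4.37 and 11.6 in 11 and between 0 and 0.323 in 7. Of the 5 upper libraries of Pttg1, 4 were also the upper ones of Cyfip2, 2.77 Mb away, and all 5 of Cyfip2 were those of Fndc9, which lies within it. A strain segment that still segregates among cK15 mice might give such levels and stays open. In a window 10 Mb wide centred on Pttg1, 0 of 16 tested genes besides Pttg1, Cyfip2 and Fndc9 had 3 times the spread of control. Elsewhere it was 11 of 10528 (Fisher exact p = 1). At that rate 0.0167 would be expected among the 16, so the count of 0, set beforehand as evidence against a segment, decides nothing. Variants acting on these genes alone were not tested and stay open too. A genotype effect alike in all cK15 libraries would not part libraries of the same group. At 12 am Pttg1 was at 124.6, 11.9 and 135.6 FPKM in cK15 replicates 1, 3 and 4, and Cyfip2 at 2.69, 3.40 and 33.5. These values argue against such an effect as the source of the 2 levels of Pttg1 and Cyfip2, though not of their lower mean.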

How the results depend on the processing

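Terms for library sets, fits within either set and the replicate block for named genes were chosen after seeing the data; the other alternatives were not. The cause of a change was not tested except where fewer libraries or a fold minimum set it. No named gene reversed, while quantile normalization turned the averaged balance from more lower to more higher genes (635 higher, 605 lower); of 166 named results, 102 did not cross the threshold in the settings run for named genes, 27 were lost without at least 1 single library and 1 was gained (Rora rhythm in control with the set term).

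For the averaged difference (1191 genes), a minimum of 1.5-fold gave 144, the random replicate block 346, terms for 2 and 3 library sets 2168 and 2479, and the 12 libraries apart alone 575 in an additive genotype and time model. In the order 12 am to 8 pm, only the 6 libraries of the time gave 65, 57, 50, 33, 65 and 47 genes, 2 sets 255, 228, 216, 151, 316 and 274, and 3 sets 335, 319, 295, 185, 413 and 349. Rhythm in control (297) became 191 at 1.5-fold, 143 with time as a factor, 136 with 24 h and 12 h periods, 44 with noon and midnight exchanged, 730 and 831 with 2 and 3 sets and 46 in the 12 apart. Rhythm in cK15 (114) became 202 with all 36 libraries in 1 fit, 42, 57 and 28 under the same 3 changes of the time model, 261 and 383 with 2 and 3 sets and 7 in the 12 apart. The rhythm difference (0 genes, limma; 291 at unadjusted p under 0.05) became 1 with time as a factor, 1 and 5 with 2 and 3 sets and 2 in the 24 other libraries. With noon and midnight exchanged, 0% of rhythmic control genes peaked around midnight, against 24.9%.

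Leaving out single libraries or replicate numbers gave 757 to 1268 genes for the average, 86 to 139, 74 to 124, 67 to 118, 50 to 84, 73 to 146 and 64 to 127 at the 6 times, 86 to 293 and 33 to 127 for rhythm in control and cK15, 0 to 1 for the difference, and -1.22 to -1.06 log2 for Klf15. Without 1 of the 6 replicate numbers, camera lost the endothelial list in 3, immediate early and proliferation in 4 each and hypertrophy in 1, and gained cardiomyocyte, oxidative phosphorylation and clock in 2 each and ion channels in 1.

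With the replicate block as a fixed term, which rests the averaged difference on the shared numbers 3 and 4 alone, the averaged count was 1172. Of 110 named genotype differences it ended 10 calls, and it changed the call of 3 gene lists, all given beside the results; it changed no other call among these. Within a genotype the number was not taken to pair libraries across times, because not all pairs correlated by over 0.1. In each genotype 35 of 45 did (lowest -0.322 in control and -0.284 in cK15). The 10 others each joined a library that stands apart with one that does not, and 1 of each was from 8 pm. The exceptions thus came with the library sets, and a series of libraries by number is not excluded. With the block, rhythm gave 470 genes in control and 202 in cK15. Depth is unknown, so no limit of detection can be given.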

Other observations

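The test of the clock offset per library was chosen only after the result was seen.

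Among other gene groups, Kruppel-like factors moved both ways: Klf10, a repressor induced by TGF-beta, fell by 0.40 (SE 0.10), Klf9 by 0.26 and Klf12 by 0.21, and Klf4 rose by 0.26 (1 higher and 3 lower of 8; 2 and 3 adjusted over the list alone; camera adjusted p = 0.680). The immediate early genes Atf3 (0.49, SE 0.092) and Nr4a1 (0.35, SE 0.12) rose, of 5 tested (2 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.172 with an estimated correlation, and 0.0594 with the replicate block). The autophagy receptor Sqstm1 rose by 0.28 (SE 0.046), while the protease Ctsl (-0.26), the mitophagy receptor Bnip3 (-0.32) and Gabarapl1 (-0.18) fell, of 15 (1 and 3 adjusted over the list alone; camera adjusted p = 0.959; median 0.018, mean -0.022). The folding genes Pdia6, Xbp1 and Pdia4 fell by 0.22 each, of 12 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.959, towards lower, with median 0.037 and mean 0.013). The replication gene Mcm2 fell by 0.26, of 5 proliferation genes (3 lower adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.260 with an estimated correlation). Median-ratio rescaling gave 1 higher and 2 lower Kruppel-like factors, and quantile normalization 2 higher and 1 lower. Calls of Klf12, Nr4a1, Klf9, Mcm2, Klf4 and Gabarapl1 were lost in 34, 34, 29, 28, 13 and 13 of 48 settings, with limma adjusted p of 0.390, 0.0884, 0.0798, 0.204, 0.0874 and 0.109 with the replicate block.

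Of the remaining markers, the atrial light chain Myl7 fell by 0.77 (SE 0.25; 1 of 2, and 1 adjusted over the list alone; camera adjusted p = 0.330), smooth muscle actin Acta2 by 0.35 (1 of 6, and 1; 0.652), the mesothelial gene Upk1b by 0.39 (1 of 4, and 3; 0.062) and the nuclear RNA Neat1 by 0.61 (1 of 4, and 2; 0.143, and 0.039 with the replicate block). The calls of Myl7 and Acta2 were lost in 24 and 29 of 48 settings, that of Myl7 with the replicate block as well (limma adjusted p = 0.130). Xist rose from 0.996 ± 0.413 to 1.69 ± 0.768 FPKM (SD, n = 18 each), 1 of 5 in the sex list (1 adjusted over the list alone; 0.330), a call lost with the replicate block (limma adjusted p = 0.104). Blood (4 tested; camera adjusted p = 0.882; median -0.038, mean 0.024), skeletal muscle (3; 0.515) and Schwann markers (1, with no set test) had 0 calls, and 0 adjusted over the list alone (limma; 1, 1 and 0 at unadjusted p under 0.05). Lymphocyte and adipocyte markers had 0 tested members, and mitochondrial genome RNA had 0 symbols in the tables.

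Each library's clock offset, the shift in hours that best placed its 14 clock genes on the curves of both genotypes together, was 0.692 ± 0.927 h in cK15 and -0.828 ± 0.628 h in control (SD, n = 18 each). The difference of 1.52 h ahead had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, and was in the same direction at 6 of 6 times. It was 1.04 h in the 12 libraries standing apart and 1.76 h in the other 24. Because the genes were chosen after their peaks were seen to differ, this describes the libraries and adds no independent evidence.

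A hypothesis was that genes linked to the targeted locus, through strain variants carried beside it, might make up part of the lower expression in cK15. Of 759 lower calls with a position, 7 lay within 10 Mb of Klf15 (0.922%), among 106 tested genes there (Fisher exact p = 1), which argues against linkage as a source of more lower calls than elsewhere.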
